A study of Mus musculus with 11 samples.

How the data were processed

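Mammary gland of wild-type mice of a mixed strain background was profiled at day 6 of pregnancy (P6), at day 13 (P13) and at parturition (L1). The labels describe 11 samples, and 3 of them entered the results: the STAT5A ChIP-seq and the H3K4me3 ChIP-seq of whole tissue at P6, and the RNA-seq of whole tissue without lymph nodes at L1. The other 8 samples, among them all input libraries, the P13 samples and the L1 ChIP-seq samples, were not used here. Each group used held 1 library, so no value has a replicate check and no p-value was computed.

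Per the labels' protocols, frozen tissue was crosslinked with formaldehyde, nuclei were purified on a sucrose gradient, chromatin was sonicated and precipitated with antibodies against STAT5A or H3K4me3, and libraries were sequenced on an Illumina HiSeq. RNA was poly(A)-selected and made into TruSeq libraries for the same instrument. For the ChIP-seq lists the submitters' processing notes name CASAVA, Bowtie, HOMER and the mouse build mm9, and for the RNA-seq CASAVA, TopHat and mm9. Their versions, the peak settings and the tool that computed the expression values are not given in the sources used here.

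The deposited STAT5A list gives each peak's position and a score, and the deposited H3K4me3 list gives each region's position and a score. These scores are the authors' own values, and the sources used here do not name their scale. Allowing 0.05 for rounding, all 8822 STAT5A scores fell on whole multiples of a step of 0.159, and 99.7% of the H3K4me3 scores on those of a step of 0.26, where evenly spread values would do so in 62.8% and 38.5% of cases, so the scores were treated as linear. They served to rank, filter and describe peaks within their own list, and for the X chromosome autosomal scores were divided by 2, also with a background of up to the lowest score left undivided. Peaks were called on single samples, per the labels. Whether an input library entered peak calling is not given in the sources used here. Coordinates below are in mm9 and count from 1.

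The authors' deposited expression table gives FPKM (fragments scaled by transcript length and by the number of mapped fragments) per locus of a transcript assembly, with a gene symbol where a locus had one. It held values of the L1 library for 30305 loci. Of these, 21958 carried 1 symbol, 117 carried several and 8230 carried none. Expression at P6 and P13 was not analysed here, so every planned comparison between stages was left out, and the level of each gene at L1 is described in its place. Neither the FPKM table nor the peak lists hold read counts, so the sequencing depth of all 3 libraries is unknown. Low FPKM values of a single library cannot give it either, since the step of 1 fragment depends on the length of each locus.

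A gene took the FPKM of its highest locus, because 3832 of the 14847 named genes had several loci. The loci with several symbols were left out of gene counts and lists. Symbols were matched to a gene table of the assembly GRCm38.p6, directly or through a unique older symbol, for 14743 of the 14847 genes. That table served only for symbols and for which genes neighbour each other. With no annotation or sequence of mm9 at hand, peaks and regions were not assigned to genes or promoters, and no binding motif was searched for.

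Before the data were examined, 23 gene lists were fixed, covering milk components, synthesis pathways, cell types of the gland and housekeeping functions. For each list the median log2(FPKM + 1) was placed among the medians of 10000 random lists of the same size, drawn from all named genes, and a list was called above or below when it left the central 95% of them. Matching on expression was not possible here because expression was itself the measure. No minimum FPKM was applied, since such a filter would select genes on the measured value. These percentiles describe 1 library. A gene is named because it belongs to the milk protein, milk fat globule or prolactin JAK STAT5 list, is among the 4 highest measured members of another list, or is among the 20 genes with the highest FPKM. The 4 highest members stand in for the 4 with the largest change between stages, which could not be computed. Single values of some genes that this rule names are not reported here. Of peaks and regions, those named are the 10 STAT5A peaks with the highest score and the 10 widest H3K4me3 regions.

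A STAT5A peak was counted as on an H3K4me3 region when they shared at least 1 bp. The share was set against 1000 random placements of the peaks on their own chromosomes, between the first and the last coordinate found there in either list. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. Peaks were also ranked by score and regions by width, and each ranking was split into 10 equal parts, with ties left in the order of the list. Peaks within 12.5 kb of another were called clustered. The length of a chromosome was taken as its last coordinate in the lists. Medians on the X chromosome have bootstrap intervals from 10000 draws.

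The overlap and distance computations were tested on simulated data, in which all 2646 peaks planted on H3K4me3 regions among 8822 were recovered. Of 200 random gene lists drawn from a simulated table of 15000 genes, 6 fell outside the central 95%. Alternatives were another overlap rule, stricter peaks or regions, pseudocounts of 0.1 and 5, an FPKM minimum of 1, the sum over loci, genes with a single locus, another background for random lists, unclustered peaks, and peaks shifted by 10 kb. The last 5 were chosen after seeing the data. All computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.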

Results

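The series followed mouse mammary tissue through pregnancy with ChIP-seq of the transcription factor STAT5A, which carries the prolactin signal to the nucleus, and of H3K4me3, a histone mark of active promoters, together with RNA-seq. The question named in its title is the order in which STAT5 binding and H3K4me3 appear at mammary genes. Analysed here were 8822 STAT5A peaks and 14738 H3K4me3 regions from tissue at P6, and FPKM values of 14847 named genes from tissue at L1, 1 library each. Because the stages differ between the assays and there are no replicates, each assay is described on its own stage, and no difference has been set against biological variation. Sequencing depth is unknown for all 3 libraries.

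Milk protein genes were among the named genes with the highest levels in the gland at parturition. The beta-casein gene Csn2 had the highest level of all named genes, at 170861 FPKM, followed by the casein genes Csn1s1 at 142389 and Csn1s2a at 72910. Below Il1rapl1, which ranked next, the whey acidic protein gene Wap reached 63664 FPKM, and Glycam1, which encodes a milk mucin-like protein, 59241. The kappa-casein gene Csn3 stood at 28095 FPKM and Csn1s2b at 7259, so that Csn2 lay 6.08 times above Csn3 and 23.5 times above Csn1s2b. Spp1 (osteopontin) reached 19351 FPKM, Expi 8186, and Lalba, the regulatory subunit of lactose synthase, 8034.

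All 15 genes of the milk protein list were measured, with a median of 8186 FPKM. Lower in the list were the amino acid oxidase gene Lao1 at 2885 FPKM, the bile salt-stimulated lipase gene Cel at 480.0, Muc15 at 292, the lactoferrin gene Ltf at 292 and the lactoperoxidase gene Lpo at 58.8. The list's median lay above all 10000 random lists, whose medians fell between 0.98 and 3.56 on the log2(FPKM + 1) scale in their central 95%, against 13.00 for the milk proteins. Together the 15 genes made up 53.2% of the summed FPKM of named loci and 24.8% of that of all loci. The difference between these shares comes from loci without a gene symbol, which held 53.3% of the summed FPKM.

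Among the 20 named genes with the highest FPKM, 10 belonged to a list fixed beforehand and 10 to none. The former were Csn2, Csn1s1, Csn1s2a, Wap, Glycam1, Csn3, Spp1, Expi and Lalba, together with the transferrin gene Trf at 11909 FPKM. The latter included Il1rapl1 at 65299 FPKM, Fam163b at 23616, 9330179D12Rik at 22593, the cardiac transcription factor gene Tbx20 at 12280 and 1700001C19Rik at 12158. Mageb16 stood at 12120 FPKM, Macrod2 at 12069, Hs6st3 at 11218, Mtrnr2l at 8257 and Xkrx at 7808. Several of these were carried by a single locus of the gene: in Macrod2 and Hs6st3 the next locus stood at 5.24 and 6.26 FPKM, and in 9330179D12Rik at 0.20. In Mageb16, by contrast, the next locus stood at 1970 FPKM. Of 20 odorant and vomeronasal receptor genes, looked at after the values were seen, 11 reached 1 FPKM and Vmn1r58 stood at 616, so a high FPKM in this table was not limited to genes known from the gland. Locus lengths were not used here, and whether the levels of Il1rapl1, Fam163b, Tbx20 and the others on no list come from very short loci was not tested. Of all named genes, 10926 reached 1 FPKM, 6574 reached 5, 440 reached 100 and 51 reached 1000, and 599 were listed at 0.

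Genes of milk fat production were also high. The milk fat globule list had a median of 395 FPKM over 10 measured genes, above all 10000 random lists. Fabp3, a fatty acid carrier, reached 2220 FPKM, Mfge8 1582, the lipid droplet coat gene Plin2 798, Cidea 723, the butyrophilin gene Btn1a1 538 and the xanthine dehydrogenase gene Xdh 251. Rab18 stood at 225 FPKM, Muc1 at 177 and Bst2 at 64.9, while the fatty acid transporter gene Cd36 stood apart at 1.85. Summed over the loci of each gene, Btn1a1 came to 994 FPKM, above Plin2 at 813 and Cidea at 723, Xdh to 413 and Cd36 to 2.78. The 24 genes of fatty acid and triglyceride synthesis had a median of 142 FPKM, again above all random lists. The desaturase gene Scd1 led them at 3584 FPKM, followed by the lipoprotein lipase gene Lpl at 973, Thrsp at 608 and the ATP citrate lyase gene Acly at 573. Adipocyte genes, given below, were also above all random lists in this whole tissue, so which cells supplied these transcripts cannot be told.

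Cholesterol synthesis, with 20 measured genes and a median of 21.3 FPKM, lay above all 10000 random lists as well. Insig1, a sterol-sensing regulator, was at 205 FPKM, and the isoprenoid pathway genes Fdps, Pmvk and Idi1 were at 143, 62.6 and 51.8. Ion and nutrient transport had a median of 45.1 FPKM over 16 genes, with Trf followed by the folate receptor gene Folr1 at 1119, the phosphate transporter gene Slc34a2 at 275 and Slc28a3 at 167, or 279 summed over its loci. This list too lay above all random lists. For lactose and glucose handling the median was 16.5 FPKM over 12 genes, at percentile 99.7 of random lists. Lalba and B4galt1, which together form lactose synthase, stood at 8034 and 436 FPKM, far above the glucose transporter gene Slc2a1 at 28.6.

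The prolactin JAK STAT5 list had a median of 14.8 FPKM over 19 genes, at percentile 99.8 of random lists. Its highest member was Elf5, an epithelial transcription factor of alveolar development, at 577 FPKM, and next came Akt1 at 169. Stat5a stood at 41.8 FPKM and Stat5b at 17.6, a ratio of 2.38. The receptor genes Ghr and Prlr were at 55.6 and 17.1 FPKM, and the kinase gene Jak2 was at 7.76. Among the feedback inhibitors of cytokine signalling, Cish reached 33.2 FPKM, which was 5.02 times the level of Socs2 at 6.61, whereas Socs3 was at 1.25 and Socs1 at 0.38. Other members ranged from Igf1 at 2.55 and Bcl6 at 2.36 FPKM (5.50 summed over its loci) through Bcl2l1 at 7.83, Ptpn1 at 10.5, Ptpn11 at 11.4 and Stat3 at 18.6 to Pim1 at 31.0.

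Markers of the luminal epithelium had a median of 25.04 FPKM over 19 genes and lay above all 10000 random lists. The keratin genes Krt19, Krt18 and Krt8 stood at 244, 179 and 129 FPKM, and the protease inhibitor gene Spint2 at 160. Basal and myoepithelial markers were at a median of 30.7 FPKM over 10 genes, percentile 99.97, with the contractile genes Cnn1 at 59.0 and Mylk at 37.1 and the keratin genes Krt14 at 54.2 and Krt5 at 37.9. Markers of hormone-sensing luminal cells were at a median of 1.24 FPKM over 15 genes, percentile 4.5 of random lists, inside the central 95%. This percentile depended on the setting: it was 52.2 with an FPKM minimum of 1, which left 9 of the genes, and 0 when only the random lists were held to that minimum. Their highest members, Id2 at 163 FPKM, Ly6a at 47.3, Ccnd1 at 28.0 and Gata3 at 24.9, are also expressed in other cells of the gland. Chosen after their values were seen, the progesterone receptor gene Pgr was at 0.31 FPKM, the estrogen receptor gene Esr1 at 4.16, and the amphiregulin gene Areg was listed at 0; summed over loci, Pgr came to 0.48 and Esr1 to 6.26.

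Transcripts of the surrounding tissue were present at the same stage. Adipocyte genes had a median of 21.5 FPKM over 20 genes, above all random lists, led by Fabp4 at 723, Cfd at 523, Acsl1 at 416 and Car3 at 389. The skeletal muscle list stood at 20.6 FPKM over 12 genes, percentile 99.9, with Tnnt3 at 37.2, Tnni2 at 27.9, Ckm at 27.6 and Mylpf at 26.8. Genes of fibroblasts and matrix were at a median of 10.2 FPKM over 19 genes, percentile 98.1, with Sparc at 132 (230 summed over its loci), Dcn at 82.6, Col3a1 at 75.03 and Postn at 70.3. This call was lost under 4 of 6 alternatives: at percentile 87.1 with an FPKM minimum of 1 or with random lists from such genes, at 96.9 with the sum over loci and at 95.7 with single-locus genes.

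The other cell type lists were not above random lists. Endothelium, at a median of 4.81 FPKM over 12 genes, fell at percentile 63.5, with Pecam1 at 15.1, Cdh5 at 14.3, Egfl7 at 9.88 and Kdr at 7.05. Brown fat fell at percentile 39.2 over 8 genes, with Cox7a1 at 76.5 FPKM, Cpt1b at 11.8, Cox8b at 7.80 and Ucp1 at 6.36. Macrophages and myeloid cells fell at percentile 23.0 over 12 genes, with Cd14 at 98.5 FPKM, Lyz2 at 62.0, Fcer1g at 8.07 and Lyz1 at 6.92. For this list the percentile was 58.9 with single-locus genes, 16.7 with an FPKM minimum of 1 and 0.48 when only the random lists were held to that minimum. Lymphocyte genes were lowest, at a median of 0.51 FPKM over 15 genes and percentile 0.25, the only list below the central 95%. Igj, the joining chain of secreted antibodies, was their highest at 19.8 FPKM, against 2.47 for Ptprc, 1.10 for Lck and 0.80 for Ltb. Lymph nodes had been removed from this tissue, per the labels. With an FPKM minimum of 1 the percentile was 9.11, but that setting leaves only 3 of the 15 genes and takes out the low values that the call rests on, so it says little about it. Of the red blood cell list only Alas2 was measured, at 1.68 FPKM, and no percentile was computed.

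Genes of protein production and energy supply lay above random lists of named genes, and cell cycle genes lay within them. The secretory pathway had a median of 68.3 FPKM over 22 genes, with the translocon-associated genes Ssr4 at 658 and Ssr2 at 482 and the chaperone genes Calr at 395 and Hspa5 at 356. Cytosolic ribosome genes had a median of 496 FPKM over 27 genes, from 110.4 to 1013, with Rplp1, Rplp0, Rps18 and Rpl7 at 1013, 959, 863 and 859. Oxidative phosphorylation stood at 76.2 FPKM over 23 genes, led by Cox4i1 at 531, Atp5o at 481, Atp5b at 466 and Ndufa4 at 286. Commonly used reference genes stood at 99.6 FPKM over 12 genes, with Eef1a1 at 2040, Ppia at 704, Actb at 356 and B2m at 308. These 4 lists lay above all 10000 random lists. Cell cycle genes had a median of 5.02 FPKM over 28 genes, percentile 73.5, with Pcna at 45.4, Mki67 at 26.5, Mcm6 at 15.5 and Tyms at 12.9. All 28 reached 1 FPKM. In all, 16 of the 22 lists with enough measured genes lay above the central 95% of random lists, 1 lay below and 5 lay within. Skeletal muscle and reference genes were among the 16, so a place above random lists alone does not mark a function of the gland or of this stage.

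**Figure D1:**
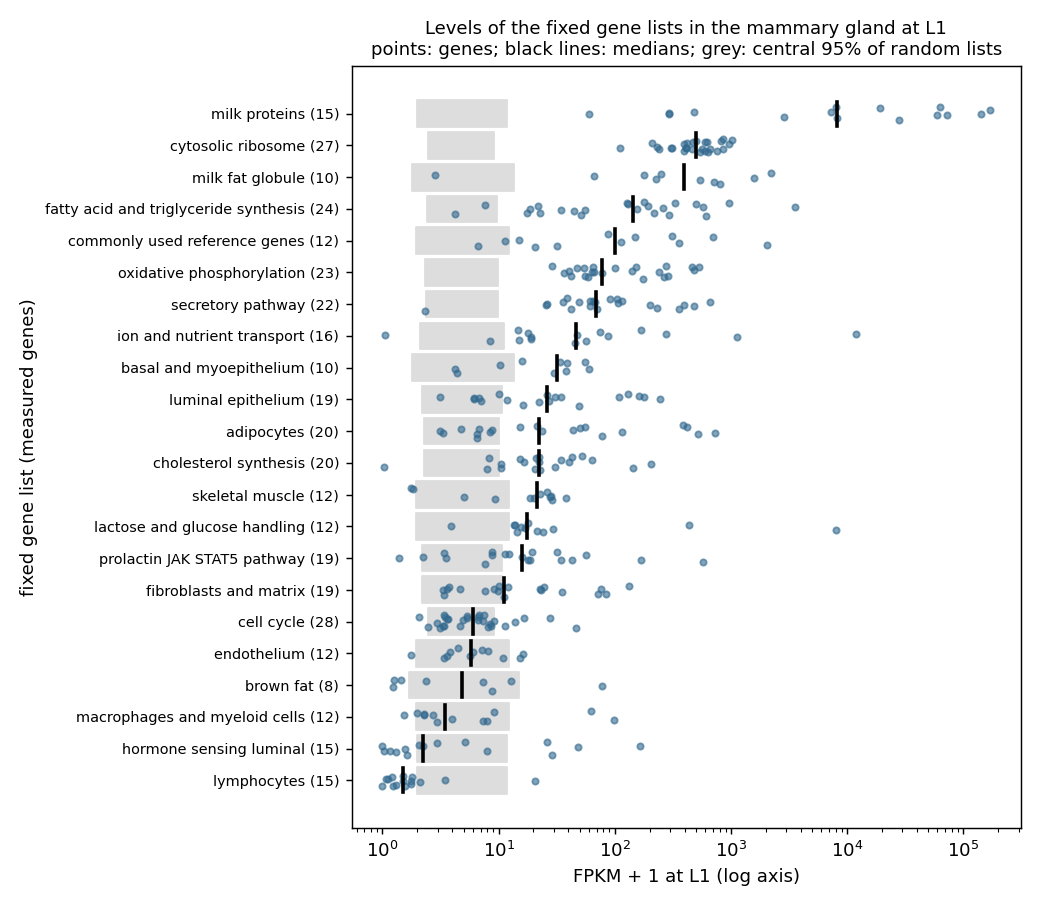
FPKM + 1 of each measured gene at L1 (log axis, 1 library) for 22 gene lists, sorted by median, with the number of measured genes in brackets; black lines are list medians and grey bands the central 95% of medians of 10000 random lists of the same size. Milk proteins stand highest at a median of 8186 FPKM and lymphocyte genes lowest at 0.51.

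At P6 the H3K4me3 regions covered 21.4 Mb of the genome, with a median width of 1318 bp and a range from 501 to 17500 bp. The widest lay on chromosome 2 from 9792287 to 9809786, the next on chromosome 13 from 72761120 to 72772455, and the next on chromosome 8 from 94878471 to 94888869, with widths of 17500, 11336 and 10399 bp. Chromosome 5 held a pair of the 10 widest regions, from 123585073 to 123594985 and from 143575416 to 143585252. The latter, 9837 bp wide, also had the highest score of all regions, 2096. The other regions among the 10 widest were on chromosome 14 from 22801753 to 22811230, on chromosome 8 from 129110877 to 129119488 and from 11001673 to 11010151, on chromosome 3 from 143861109 to 143869197 and on chromosome 1 from 82280893 to 82288847. Width and score rose together across regions (Spearman's rho 0.84; regions are not independent replicates). Of all regions, 1608 (10.9%) had the minimum width of 501 bp and 72 were wider than 5 kb. What these regions hold in mm9 was not analysed here.

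STAT5A peaks had a few very high scores and many near the minimum. Every peak was 215 bp wide, and scores ran from 4.3 to 121.3 with a median of 6.0 and quartiles of 4.9 and 8.1. The highest score belonged to a peak on the X chromosome from 73844303 to 73844517, followed by peaks on chromosome 3 from 5860578 to 5860792, with a score of 111.4, and on chromosome 5 from 147072531 to 147072745, with a score of 96.1. On chromosome 11, 4 of the 10 highest peaks stood close together, starting at 3052545, 3074270, 3096730 and 3099017, with scores from 47.6 to 55.4. The rest of the 10 started at 35981716 on chromosome 16, at 140503456 on chromosome 1 and at 109484439 on X, with scores of 53.6, 46.9 and 44.6. None of these 10 peaks lay on an H3K4me3 region, and their distances to the nearest region ran from 0.80 to 723 kb.

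A minority of STAT5A peaks lay on H3K4me3 regions in P6 tissue. Without an input library or a motif search, whether each peak marks STAT5A binding was not tested. Both ChIP-seq libraries came from whole tissue, so peaks and regions of different cell types are pooled. Of the 8822 peaks, 1796 (20.4%, 95% interval 19.5 to 21.2) lay on an H3K4me3 region, against a median of 1.02% over 1000 random placements, which ranged from 0.66% to 1.46%. The observed share was 19.96 times the random one. Conversely, 1718 of the 14738 regions (11.7%, interval 11.1 to 12.2) held a STAT5A peak, against 0.61% at random, and 75 of them held at least 2 peaks. Against the same peaks moved by 10 kb to either side, of which 2.37% met a region, the ratio was 8.59, and it was 11.6 when a peak centre within 1 kb of a region counted as a hit.

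Most STAT5A peaks away from H3K4me3 were nonetheless within 100 kb of a region. Over all peaks, the median distance from a peak to the nearest region was 19.8 kb, against 116 kb for randomly placed peaks. Within 10 kb of a region lay 39.1% of peaks against 11.4% at random, and within 100 kb 81.8% against 47.1%, so that 1606 peaks (18.2%) lay farther than 100 kb from any region. Where the centre of a peak fell inside a region, it was in the inner 50% of the region's width in 938 of 1693 cases (55.4%, interval 53.0 to 57.8), above the 50% of an even spread.

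The STAT5A peaks with the highest scores were those least often on H3K4me3. In the weakest of 10 equal score groups, with scores from 4.3 to 4.5, 274 of 883 peaks (31.0%, interval 28.0 to 34.2) lay on a region. In the strongest, with scores from 11.1 to 121.3, 69 of 883 did (7.81%, interval 6.13 to 9.79). The share was lower in each successive group, and the difference of 23.2 percentage points between the outer groups exceeded their counting intervals. Even the strongest group lay on regions 7.66 times as often as random placements. The median score was 5.4 for peaks on H3K4me3 and 6.2 for peaks off it, with quartiles of 4.8 and 6.7 against 5.1 and 8.4. No input library was used here. Whether high scores off H3K4me3 come from STAT5A binding or from repeated sequence was therefore not tested.

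**Figure D2:**
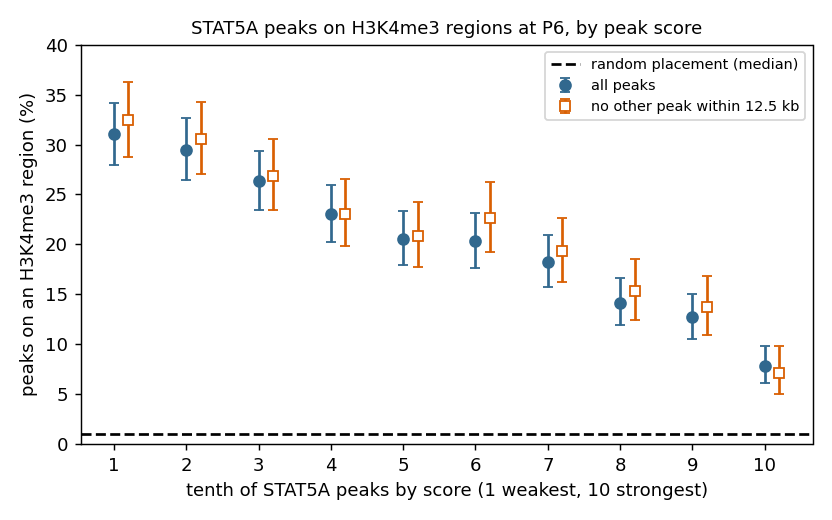
Percent of STAT5A peaks on an H3K4me3 region at P6 (vertical axis) in 10 groups of peaks from the weakest (1) to the strongest score (10); circles are all peaks, squares unclustered peaks, bars exact 95% intervals covering counting error, and the dashed line the median of 1000 random placements. The share falls from 31.0% to 7.81% over all peaks and stays above the random 1.02% throughout.

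Wide H3K4me3 regions held a STAT5A peak more often than narrow ones. In the narrowest of 10 equal width groups, where all regions were 501 bp wide, 51 of 1474 regions (3.46%, interval 2.59 to 4.52) held a peak, and in the widest, from 2421 to 17500 bp, 322 of 1474 did (21.8%, interval 19.8 to 24.0). Random placement gave 0.27% and 1.22%, so the ratio to random was 12.8 in the narrowest group and 17.9 in the widest. In the third group, from 765 to 957 bp, the ratio was 24.0, and in the sixth 23.6. The random medians correspond to few regions per group, so these ratios move in coarse steps and their exact order is uncertain. Per Mb of marked sequence, the narrowest group held 70.4 peaks, the third 95.3, the seventh 95.35 and the widest 75.6. These densities count peaks from 1 bp of overlap but divide by the regions' own width, which raises narrow regions most. With the peak centre inside the region, 2.58% of the narrowest and 21.4% of the widest regions held a peak. Sorted by score instead, the weakest group of regions held 65.1 peaks per Mb, the second 56.7, the ninth 99.5 and the strongest 94.8, and the ratio of the strongest to the weakest was 1.45 (exact interval 1.08 to 1.99). The density of the weakest group, with a median width of 501 bp, is raised in the same way. With only the higher-scoring 50% of peaks, the shares of the narrowest and widest groups were 1.70% and 8.68%, and without clustered peaks 2.24% and 14.5%. Fewer peaks were counted in both settings. The higher-scoring peaks also lay on regions less often, in 14.6% of cases against 20.4% of all peaks.

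**Figure D3:**
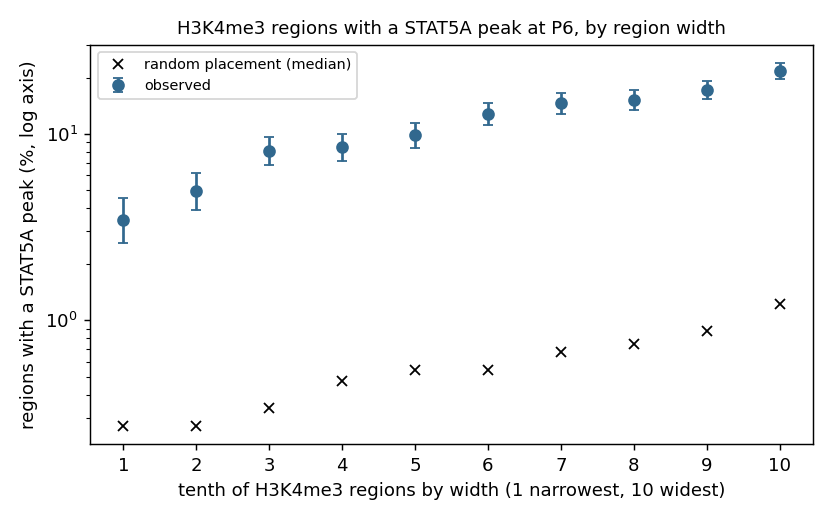
Percent of H3K4me3 regions with a STAT5A peak at P6 (log axis) in 10 groups from the narrowest (1) to the widest regions (10); circles are observed shares with exact 95% intervals covering counting error, and crosses the median of 1000 random placements of the peaks. Observed shares run from 3.46% to 21.8% and random ones from 0.27% to 1.22%.

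The X chromosome carried few STAT5A peaks. Its 87 peaks made 0.52 per Mb (exact Poisson interval 0.42 to 0.64), against 3.54 per Mb on the 19 autosomes together, a ratio of 0.15 (0.12 to 0.18). The autosomes ranged from 2.58 per Mb on chromosome 14 to 5.27 on chromosome 11. H3K4me3 regions were also sparser on X, at 2.66 per Mb against 5.79 on the autosomes together, but less so, so that X had 0.20 STAT5A peaks per region where autosomes had from 0.47 to 0.84. The H3K4me3 regions of X had a median score of 125.5, against 200.7 to 234.7 on single autosomes. Of the STAT5A peaks on X, 10.3% (interval 4.84 to 18.7) lay on H3K4me3, and on autosomes from 13.5% on chromosome 13 to 28.8% on chromosome 7.

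**Figure D4:**
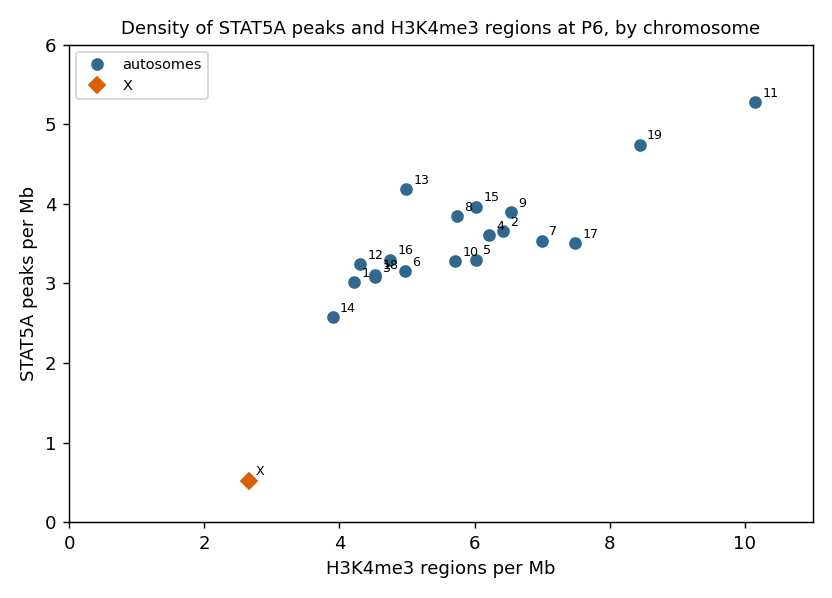
STAT5A peaks per Mb (vertical axis) against H3K4me3 regions per Mb (horizontal axis) at P6 for each chromosome, 1 library per antibody; circles are autosomes and the diamond is X. Chromosome 11 stands highest, at 5.27 peaks and 10.1 regions per Mb, and X lowest, at 0.52 and 2.66.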

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

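The overlap of STAT5A peaks with H3K4me3 at P6 stayed far above random placement under each alternative run, but its size moved. The share of peaks on regions was 19.2% with at least 50% of the peak covered, 14.6% for the higher-scoring 50% of peaks, 15.2% for the higher-scoring 50% of regions, 24.1% with a peak centre within 1 kb of a region and 21.7% without clustered peaks. The ratio to random placement under these settings, in the same order, was 21.7, 14.4, 22.7, 11.6 and 21.5, and 8.59 against peaks shifted by 10 kb. The narrowest regions held a peak in 2.58% of cases with the peak centre inside, 1.70% with the higher-scoring 50% of peaks and 2.24% without clustered peaks. The widest held a peak in 8.68% and 14.5% under the last pair of settings, into which fewer peaks entered. The unclustered and shifted settings were chosen after seeing the data.

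Of the lists at L1, none lay below random lists with an FPKM minimum of 1 (a count of 0), and 3 did when random lists were drawn from genes with at least 1 FPKM, a background chosen after seeing the data. The former takes low genes out of the lists, leaving 3 of 15 for lymphocytes, and the latter takes them out of the random lists alone, which pushes every list down by construction. A pseudocount leaves the order of genes as it is and moved no call. Over all alternatives, 125 of the percentiles of single lists kept their call, 5 lost it, 4 of them of fibroblasts and matrix and 1 of lymphocytes, and 2 gained one, those of hormone-sensing luminal cells (percentile 0) and of macrophages and myeloid cells (0.48) with random lists from genes with at least 1 FPKM. With that minimum on both sides these lay within, at 52.2 and 16.7. That setting takes low genes out of the lists, leaving 9 of 15 and 10 of 12, so neither setting decides whether these lists are low. In the main setting they lay within, at 4.5 and 23.0. None reversed.

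No paired analysis was possible because each group had 1 library. Changes between stages, genes near peaks and the STAT5 motif, with their other windows, pseudocounts, fold rules, scalings and matching set before the data were examined, were not run, since the P6 and P13 expression values and an annotation of mm9 were not used here. Unknown depth and single libraries limit all values: how many weak peaks or lowly expressed genes a deeper library would add was not tested.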

Other observations

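All tests in this part were chosen after the patterns they address had been seen. The genes and regions named here were picked after their values were seen.

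Most genes next to the milk protein genes in the order of measured genes stood far below them at L1, but not all. Before the casein cluster, Sult1d1 stood at 5.66 FPKM, between Csn1s2b and Csn3 Prr27 at 0.86 and Odam at 1.41, and beyond Csn3 Prol1 at 0.60 and Jchain at 19.8, while Csn2, Csn1s1 and Csn1s2a stood at 170861, 142389 and 72910. Wap lay between Tbrg4 at 14.4 FPKM and Ramp3 at 3.73, and Lalba between Zfp641 at 1.39 and Olfr279 at 1.05. Some neighbours exceeded the median named gene at 3.90 FPKM, such as Wfdc17 at 52.7 beside Expi, Ralgds at 34.8 beside Cel and Slc2a1 at 28.6 beside Lao1. Dynll2 at 54.2 came close to Lpo at 58.8, and Nop10, within 2 places of Muc15 at 292, stood at 139. Places counted only measured genes with a matched symbol and had no limit of distance. Some of these genes may therefore lie far from the milk protein gene. A hypothesis that whole neighbourhoods are expressed with the milk protein genes was tested on the 44 other genes within 2 places of 15 milk protein genes. Their median was 3.77 FPKM, at percentile 45.3 of random lists, with 1 gene, Nop10, above 100 FPKM. These values argue against it at this stage for neighbours chosen in this way.

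STAT5A peaks gathered in clusters at P6. Of the 8822 peaks, 2896 had another nearby and counted as clustered (32.8%, interval 31.8 to 33.8), against 8.94% at random. The largest cluster held 16 peaks on chromosome 1 from 90145583 to 90206551 with a median score of 9.3, and the next held 15 on chromosome 8 from 19917509 to 19964175 with a median score of 13.8 and none on H3K4me3. Clustered peaks lay on H3K4me3 in 17.5% of cases and the others in 21.7%. Whether repeated sequence gives rise to these clusters was not tested.

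The fall of the H3K4me3 share with STAT5A score was set against a pair of technical explanations. Crowding of strong peaks is argued against as the cause. Without clustered peaks the gap between the outer groups was 24.1 percentage points, against 23.2 with all peaks. That setting cannot decide on repeated sequence, since peaks in repeats that stand alone would remain in it, and no input library was used here. Weak signal from open chromatin at strongly marked regions stays open: the scores of the 1796 overlapping peaks did not rise together (Spearman's rho -0.044, bootstrap interval -0.092 to 0.0044), but these peaks lie near the lowest score, at a median of 5.4 against 4.3, which limits that test. Peaks per Mb of marked sequence were 1.45-fold higher (1.08 to 1.99) in the strongest than in the weakest regions. That ratio cannot decide, since STAT5A binding at strongly marked regions would raise it as well. No biological explanation was tested, since it would need gene positions in mm9.

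The scarcity of STAT5A peaks on X goes beyond that of marked regions, since X had 0.20 peaks per H3K4me3 region (0.16 to 0.24), below the lowest autosome at 0.47. A signal on X at the level of a single active copy may account for the low H3K4me3 scores. Their median was 125.5, with an interval (117.6 to 130.1) that included the 123 of autosomal scores divided by 2. Regions on X were also narrower, at a median of 1150 bp against 1271 to 1393 bp on single autosomes, and score rose with width. The match of scores alone therefore does not single out copy number. This division would leave 87.9% of autosomal regions, so it would cover little of the lower number per Mb on X, 2.66 against 5.79. For STAT5A the same division would leave 21.7% of autosomal peaks and so 128 of the 589 peaks that X would hold at the autosomal number per Mb, against 87 found (69.7 to 107.3), if scores hold no background; with a background at the lowest score left undivided, 100% would remain and none of the scarcity would be covered, and the background was not measured here. The peaks that X does hold had a median score of 7.0 (6.0 to 7.8), against 5.4 after division, or from 5.15 to 5.465 with a background left undivided. Without clustered peaks the median was 6.5 (5.9 to 7.8) against 5.35, or from 5.1 to 5.38. These values argue against division as the whole cause only if it acted on all peaks of X alike. Peaks with scores that do not follow the number of active copies would also raise the median on X, and they were not looked for. Reads on X being harder to place cannot be told apart from biology here, because the input library was not used and the 2.66 H3K4me3 regions per Mb on X, fewer than on any autosome, decide nothing alone.

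Loci without a gene symbol held some of the highest values at L1, 78 of the 131 loci with at least 1000 FPKM, up to 375232 FPKM, above Csn2. Run-on from an abundant neighbour is argued against for most of them, since 11.5% (5.41 to 20.8) had an adjacent locus with at least 100 FPKM. The higher adjacent locus had a median of 0.92 FPKM. How often other loci have such an abundant neighbour was not computed, so run-on at a minority of these loci stays open. Few fragments on very short loci may be a source but stay open: 16.7% of these loci (9.18 to 26.8) repeated the value of another locus to the last digit, against 3.77% (0.46 to 13.0) of named loci at that level, where the intervals overlap, and 1.76% (0.71 to 3.59) of named loci between 100 and 1000 FPKM. Loci without a symbol between 100 and 1000 FPKM repeated values as often, at 18.6% (12.1 to 26.9), so the repeats were not particular to the highest values, and identical copies of a sequence would also give them. Among named loci, Accn1 and Zfp804b shared 1055.99 FPKM, and no biological explanation was tested.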
